A study of Homo sapiens with 6 samples.

How the data were processed

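RNA-seq gene tables of 6 libraries of KGN cell clones were used, 3 of genotype FOXL2 WT/WT and 3 of genotype FOXL2 WT/C134W, with groups taken from the genotype labels. Per the labels' protocols, libraries were made with a stranded mRNA kit from RNA of high integrity. The deposited tables hold, per the file headers, the expected count, the TPM and the FPKM of each gene as RSEM writes them. The expected count is RSEM's unscaled estimate of reads per gene, deposited by the authors with decimals because reads that fit several genes or transcripts are shared out. TPM, per the file headers, is scaled by effective gene length and to the same sum in each library by the authors. FPKM, scaled per the file headers by length and by mapped fragments, was deposited too and not used for any result. The submitters' processing notes name STAR 2.7.6a, Picard 2.8.1, RSEM 1.3.1, R 3.6.3 and DESeq2 1.26.0 without their roles. The same notes name the mouse build GRCm38, although all 58336 gene IDs in the tables are human Ensembl IDs. The human build, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain. Genes with near-identical copies, such as histone genes and mitochondrial genes with nuclear copies, are uncertain because their reads can be shared out between copies.

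Gene symbols, types and coordinates (GRCh38) came from GENCODE release 29, in which 58216 of the gene IDs and 99.96% of the transcript IDs were found. Expected counts were rounded to whole numbers. Totals ran from 35332727 to 46613068 per library, so 3 counts equal between 0.0644 and 0.0849 CPM, and this covers counting error only.

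The comparison between genotypes was fixed before the data were examined. It used the 4 libraries whose title names 1 clone, because the title of the third library of each genotype joins the names of the other 2 and may stand for a mix. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold change is WT/C134W over WT/WT, and every CPM value is TMM-normalised over the 6 libraries. Every SE is the size of the log2 fold change divided by the square root of the F value of edgeR's test. That F shares information on spread across genes, so the SE does not come from the clone values of the gene alone. Gene lists, 42 in number, were written before the data were examined and tested with camera on limma 3.58.1 voom values with a preset correlation of 0.01, beside an estimated correlation and fry, where at least 3 members were tested. The lists cover FOXL2 targets, steroidogenesis, granulosa, Sertoli, theca, leukocyte, endothelial, epithelial, fibroblast and germ cell markers, growth factor and developmental signalling, the cell cycle, p53, stress, metabolism, immunity, matrix, HOX genes, forkhead factors, neuronal and cilium genes and histones. Lists without a call that are not described with the results are interferon response (adjusted p = 0.0956), BMP response (0.168), cholesterol synthesis (0.306), epithelial to mesenchymal markers (0.438), HOX genes (0.47), apoptosis regulators (0.47), Wnt pathway (0.47), histones (0.47), forkhead factors (0.508), glycolysis and hypoxia (0.508), growth factors (0.562), cilium genes (0.596), neuronal genes (0.723), antigen presentation (0.849), oxidative stress (0.866), lipid synthesis (0.866) and cyclins (0.995), all by camera with the preset correlation.

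Named genes followed a rule fixed before the data were examined. It takes FOXL2, then the 12 largest rises and 12 largest falls among called protein-coding genes with a mean of at least 2 CPM, no overlap between the genotypes in the 4 single clones and the same sign between the joined libraries. With 0 genes called, the rule's fallback applied, the 12 smallest unadjusted p in each direction under the same other conditions, so these genes are given as values and not as changes. Up to 4 members with the smallest p were named from each list, and CDKN1A was named under the cyclin list as well as the p53 targets. A share of 33.3% of genes would show no overlap between 2 groups of 2 by chance. Genes of the Y chromosome were left out of the names.

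The mixture check took genes at least 4-fold apart between the 2 clones of a genotype with at least 5 CPM in one of them, on the linear CPM scale. GC content and length of a gene are means over its GENCODE transcripts, and every tested member of each list had a value. Alternatives were all 6 libraries, DESeq2 1.42.0, limma voom, median-ratio size factors, library totals alone, no low-count filter, a filter of 10 CPM in at least 2 libraries, each library left out in turn, a block pairing 44a with 44b and 4.72 with 3.11, and limma on log2(TPM + 1). The others were log2(TPM + 0.1), no TPM filter, stricter thresholds, a test against a 1.5-fold change, and 8-fold in the mixture check. A correction for GC content by loess in each library was added after the data were seen.

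The tests were tested on simulated data with the means, library totals and dispersions of the 16416 genes, 5 simulations each. Each gene varied on its own between simulated clones, and simulated mixes differed from their clones by the mixing shares and counting noise alone. With 200 genes changed between WT/C134W and WT/WT, edgeR on 4 clones recovered 10.3% of 2-fold, 51.9% of 4-fold and 65.7% of 8-fold changes, with 13 false calls on average. With no gene changed it called 7.4 genes on average, DESeq2 51.8, limma voom 2.6, and edgeR on 4 clones plus 2 mixes of them 521.2 (452 to 566). With 6 independent clones edgeR called 1. A simulated shifted list of 30 genes passed camera with either correlation, fry and fry's mixed test in 5 of 5 simulations. An unshifted list passed camera in 0 of 5, and fry and its mixed test in 1 of 5 each. With each gene varying on its own, these simulations cannot show how often the preset correlation calls unshifted lists whose genes vary together.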

Results

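RNA was sequenced from clones of KGN, a cell line derived from a human ovarian granulosa cell tumour that carries 1 mutant and 1 wild-type copy of FOXL2, a forkhead transcription factor of ovarian granulosa cells. In 3 libraries the C134W mutation had been reverted with CRISPR/Cas9 (FOXL2 WT/WT), and 3 libraries came from cells that kept it (FOXL2 WT/C134W). RNA was taken 30 h after a transfection that the labels do not describe. The question was which genes differ in expression between cells with and without the C134W protein change. The WT/WT libraries are named 44a (replicate 1), 4.72 (replicate 2) and 4.72-44a (replicate 3), and the WT/C134W libraries 3.11 (replicate 1), 44b (replicate 2) and 3.11-44b (replicate 3). The third name of each genotype joins the names of the other 2, so the comparison between genotypes rests on the 4 libraries that each name 1 clone, 2 per genotype. The labels do not say from how many cultures each library came, so p-values of single genes measure the spread between these clones. Camera's p-values with the preset correlation take the genes of a list as nearly independent and do not measure that spread. Editing is recorded in the labels of the WT/WT samples alone, so genotype and the editing procedure cannot be separated. Summed expected counts were 46613068, 45065832 and 41923218 in WT/WT and 38288177, 42137567 and 35332727 in WT/C134W. At these depths 3 counts equal between 0.0644 and 0.0849 CPM (counts scaled to a common library total). The 50 most abundant genes took 25.55%, 27.39% and 26.33% of the counts in WT/WT against 21.47%, 20.5% and 20.62% in WT/C134W, and mitochondrial genes took 6.71%, 5.53% and 6.14% against 5.12%, 5.5% and 5.89%.

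FOXL2 itself (ENSG00000183770, chromosome 3, 138944224 to 138947140 on the minus strand, GRCh38) was transcribed at a low level in both genotypes. Its normalised level was 7.40 CPM in 44a and 4.84 CPM in 4.72, against 9.30 CPM in 3.11 and 10.1 CPM in 44b. The joined libraries held 4.35 CPM (WT/WT) and 6.35 CPM (WT/C134W). The log2 fold change, WT/C134W over WT/WT, was 0.67 ± 0.34 (SE derived from edgeR's F value, 2 clones per genotype). Its adjusted p was 0.726 in edgeR's quasi-likelihood test. A gene count does not show which allele a transcript came from, so these values do not check the genotype itself.

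Among single genes, the smallest unadjusted p belonged to C1orf198 and FBXO32, both at lower levels in the mutant clones. FBXO32 encodes a ubiquitin ligase known from muscle wasting. C1orf198 (chromosome 1, 230837119 to 230869589) had 173 ± 20.6 CPM in WT/WT and 32.1 ± 6.07 CPM in WT/C134W (mean ± SD, n = 2), a log2 fold change of -2.43 ± 0.21 (SE). FBXO32 (chromosome 8, 123497889 to 123541206) had 42.4 ± 5.54 CPM against 7.46 ± 1.19 CPM, a log2 fold change of -2.51 ± 0.22. CCN3, a matricellular protein, had the largest log2 fold change of the 12 genes named in this direction, -2.99 ± 0.34, from 17.1 to 2.15 CPM. HBEGF, a ligand of the epidermal growth factor receptor, had 27.5 CPM in WT/WT and 7.30 CPM in WT/C134W. EGR1, an immediate early transcription factor, had 62.6 and 17.0 CPM, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, had 60.1 and 27.6 CPM. ITGAV, the integrin alpha V chain, was measured at 508 ± 12 CPM and 223 ± 6.28 CPM. DACT1, a regulator of Wnt signalling, CRIP2, SSC5D, KCTD20 and ZFAND5 had log2 fold changes of -1.60, -2.62, -1.44, -1.36 and -1.25.

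In the other direction, IGFBP5, a secreted protein that binds insulin-like growth factors, was the most abundant of the 12 genes named. It had 308 ± 41.2 CPM in WT/WT and 649 ± 49.2 CPM in WT/C134W (mean ± SD, n = 2), a log2 fold change of 1.08 ± 0.19 (SE). CCNG1 and EDA2R, both transcriptional targets of p53, had log2 fold changes of 1.07 and 1.20. KIAA1217 had the largest value named in this direction, 2.02 ± 0.31, from 4.49 to 18.2 CPM. EPHB2, an ephrin receptor, had 45.1 CPM in WT/WT and 99.3 CPM in WT/C134W, and MEST, an imprinted gene, had 27.9 and 68.8 CPM. JADE2, PKIA, KIF13B, TRIM22, AOX1 and MPP4 had log2 fold changes of 1.32, 1.19, 1.33, 1.11, 1.42 and 1.61.

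**Figure D1:**
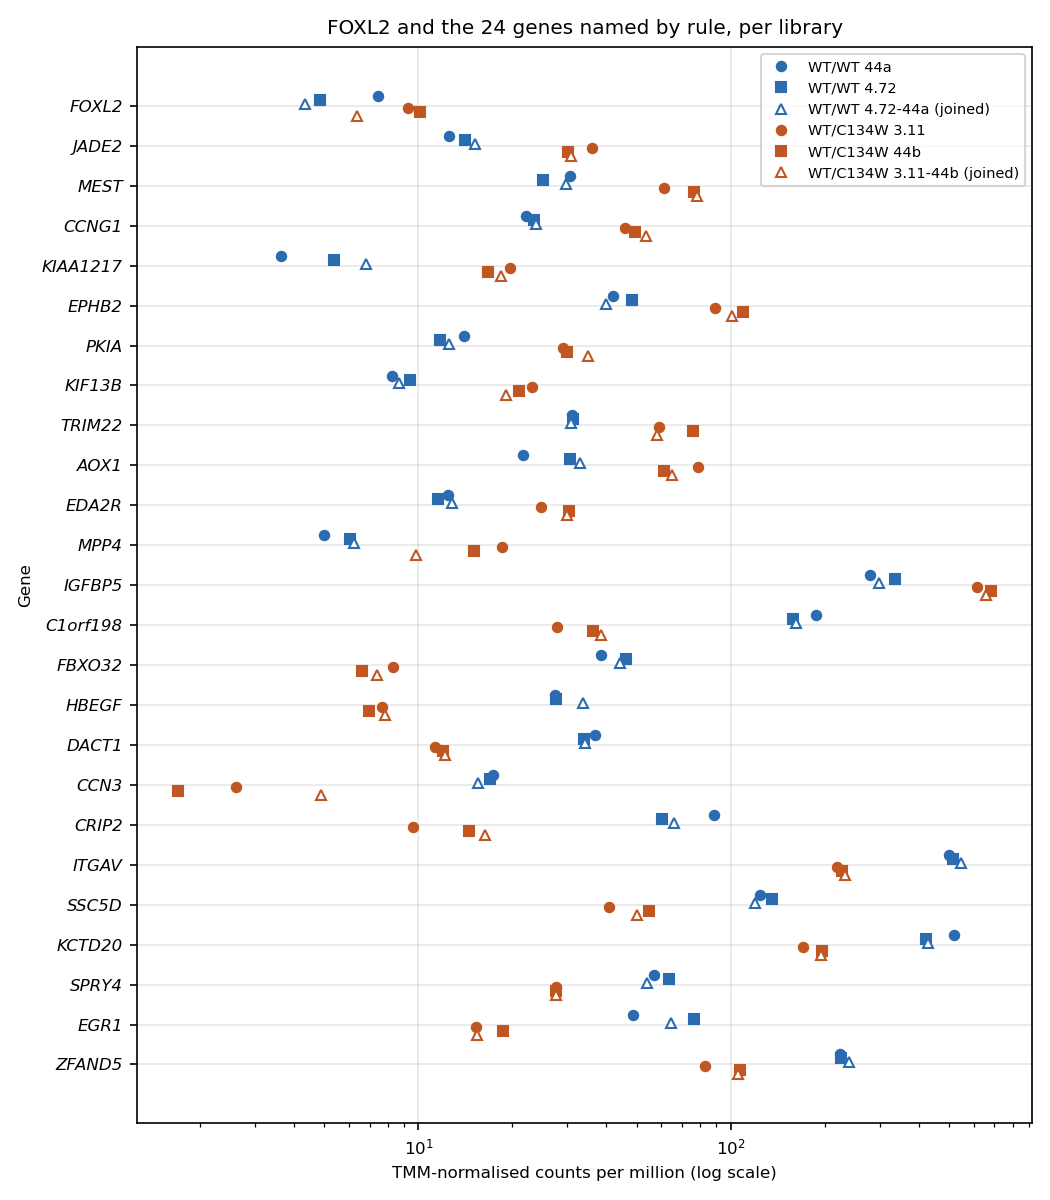
TMM-normalised CPM (log axis) of FOXL2 and the 24 genes named by rule in each of the 6 libraries, WT/WT in blue and WT/C134W in orange; open triangles are the joined libraries. As the naming rule required, the 2 mutant clones lie on one side of the 2 reverted clones for each of the 24 genes, as at C1orf198 with 188 and 158 CPM against 27.8 and 36.4 CPM.

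None of these single genes passed the threshold in edgeR's test on the 4 single clones with the low-count filter and without a block. Of 16416 genes tested with edgeR's quasi-likelihood test on the 4 single clones, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.324, at C1orf198 and FBXO32. An unadjusted p under 0.05 was found for 1243 genes, 7.57% of those tested. The count was also 0 with limma voom, whereas DESeq2 called 283 genes (69 higher and 214 lower in WT/C134W), among them all 24 genes named above. Without the low-count filter edgeR called 664 genes, all 24 again among them, but its prior degrees of freedom went from 3.71 to infinite. The 24 genes were chosen by small p in these same 4 clones, so calls for them in other tests there add no separate support. With a block that paired 44a with 44b, whose names share a stem, and 4.72 with 3.11, edgeR called 5 genes, among them C1orf198, FBXO32 and CRIP2. The labels do not say that these clones are paired. With the joined libraries added as replicate 3 of each genotype, edgeR called 511 of 16046 genes, 132 higher and 379 lower. That fit takes the joined libraries as separate clones. Simulated data with no genotype effect, in which 2 of 6 libraries were mixes of the other 4, gave 521.2 calls on average. Those mixes carried counting noise alone. An unadjusted p under 0.05 was found for 24.38% of the simulated genes, against 18.87% in the real fit with the joined libraries.

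Genes of the G2 and M phases of the cell cycle were higher in the mutant clones. All 25 tested members had a positive fold change, with a median log2 value of 1.07, and the list passed camera's competitive test with a preset correlation (adjusted p = 4.9e-17). The call was lost with an estimated correlation (adjusted p = 0.52). TTK, a spindle checkpoint kinase, had 22.5 and 16.8 CPM in the reverted clones and 48.4 and 34.0 CPM in the mutant clones, and CENPE, a kinetochore motor, had 42.6 and 27.2 against 141 and 68.1 CPM. PTTG1 and BUB1 had log2 fold changes of 1.49 and 1.25. Of the 25 members, 0 passed over all genes and 0 adjusted over the list alone. The difference in mean log2 CPM of the list between genotypes, 1.11, was 0.69 without 4.72 and 0.68 without 3.11. The list also passed camera, at 1.7e-11, when 44a and 3.11 were set against 4.72 and 44b, a split that crosses the genotypes, although the mean of 44a lay below that of 44b there. Targets of p53 were higher as well: 24 of 26 members had a positive fold change, with a median of 0.66 (adjusted p = 1.41e-08, and adjusted p = 0.52 with an estimated correlation). Without 44b the difference in mean log2 CPM was 0.31 in place of 0.59, and camera's adjusted p was 0.0249. Adjusted over the list alone, 5 members passed in edgeR's test, among them CCNG1, EDA2R, RRM2B and DDB2. RRM2B, a subunit of ribonucleotide reductase, had 19.9 and 18.2 CPM in the reverted clones and 33.9 and 39.8 CPM in the mutant clones. CDKN1A, which encodes the inhibitor p21, had 171 and 241 CPM in the reverted clones and 241 and 559 CPM in the mutant clones.

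Collagen and other matrix genes were lower in the mutant clones. Of 32 tested members 30 had a negative fold change, with a median log2 value of -0.94 (camera adjusted p = 2.02e-12, and adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone, 12 members passed in edgeR's test, and 0 passed over all genes. Between genotypes the mean log2 CPM of the list differed by -0.84, and by -0.53 without 44a. COL1A1, the most abundant transcript of 44a, had 25180 and 20840 CPM in the reverted clones and 10720 and 9847 CPM in the mutant clones. The 50 most abundant genes, COL1A1 among them, took 25.55% and 27.39% of the counts in the reverted clones and 21.47% and 20.5% in the mutant clones. COL3A1, COL5A2 and COL6A3 had log2 fold changes of -1.36, -1.18 and -0.94. Fibroblast and stromal markers were lower in 12 of 13 members, with a median of -1.16 (camera adjusted p = 6.52e-07, and adjusted p = 0.425 with an estimated correlation), and 4 passed adjusted over the list alone. The list is not separate from the matrix list: 6 of its 13 members, COL1A1 and COL3A1 among them, and 3 of the 4 that passed belong to both. Its difference in mean log2 CPM was -1.25, against -0.79 without 44a and -0.74 without 3.11. ACTA2, the smooth muscle actin, had 2741 and 6085 CPM against 537 and 1210 CPM. Metalloproteases and their inhibitors were lower in 15 of 19 members (median -0.41, camera adjusted p = 0.00572, adjusted p = 0.425 with an estimated correlation), and 1 passed adjusted over the list alone. The genotypes overlapped in the mean of this list, with 4.72 below 44b. Their difference, -0.46 in log2 CPM, was -0.06 without 44a, -0.16 without 3.11, -0.86 without 4.72 and -0.76 without 44b. The 1 member was MMP14, a membrane-bound matrix protease, at -1.07 ± 0.17, while ADAMTS1 stood at 0.85 ± 0.21.

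Genes of the TGF-beta and activin response were lower in 22 of 26 members, with a median log2 fold change of -0.88 (camera adjusted p = 1e-10, and adjusted p = 0.425 with an estimated correlation). Without 3.11 the difference in mean log2 CPM was -0.58 in place of -0.90. Adjusted over the list alone, 8 passed in edgeR's test. They were led by JUNB, an AP-1 subunit, with 118 and 66.4 CPM in the reverted clones and 23.2 and 26.6 CPM in the mutant clones, by TGFB1, the ligand itself, at -1.03 ± 0.17, and by LMCD1 at -2.05 ± 0.35. The list is not separate from others: it shares 2 members with the matrix list and 1, JUNB, with the immediate early list, all among the 8. It also shares 2 with the Hippo list and 2 with the granulosa markers, and 0 of those passed. Hippo pathway targets were lower in 15 of 21 members (median -0.59, camera adjusted p = 0.000292, adjusted p = 0.425 with an estimated correlation), with ARHGEF17 at -0.89 and AJUBA at -0.81, the 2 members that passed adjusted over the list alone. For the Hippo list the difference was -0.55, with -0.22 without 3.11 and -0.87 without 44b. Genes of the NF-kappaB and cytokine list were lower in 12 of 18 (median -0.40, camera adjusted p = 0.0011, adjusted p = 0.425 with an estimated correlation), and 0 passed adjusted over the list alone. The difference in mean log2 CPM, -0.58, was -0.28 without 4.72 and -0.88 without 44a. Of this list, IL11 had 45.2 and 59.5 CPM against 9.47 and 20.4 CPM, and TNFRSF11B 63.5 and 125 CPM against 27.0 and 35.7 CPM.

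Genes of the unfolded protein and amino acid response were lower in 23 of 24 members, with a median of -0.55 (camera adjusted p = 1.06e-07, and adjusted p = 0.425 with an estimated correlation), and 0 passed adjusted over the list alone. CHAC1, which encodes a glutathione-degrading enzyme, had a log2 fold change of -2.26 ± 0.46. ATF4, a transcription factor of this response, had a log2 fold change of -0.71 and XBP1 of -0.69. All 13 mitochondrially encoded genes had negative fold changes, with a median of -0.39 (camera adjusted p = 3.08e-06, adjusted p = 0.52 with an estimated correlation), and 0 passed adjusted over the list alone. The share of counts in mitochondrial genes was 6.71% and 5.53% in the reverted clones and 5.12% and 5.5% in the mutant clones. The unfolded protein list passed camera as well when 44a and 3.11 were set against 4.72 and 44b (adjusted p = 0.00493). The p53 and mitochondrial lists did so when 44a and 44b were set against 4.72 and 3.11 (adjusted p = 0.0253 and 0.0444).

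**Figure D2:**
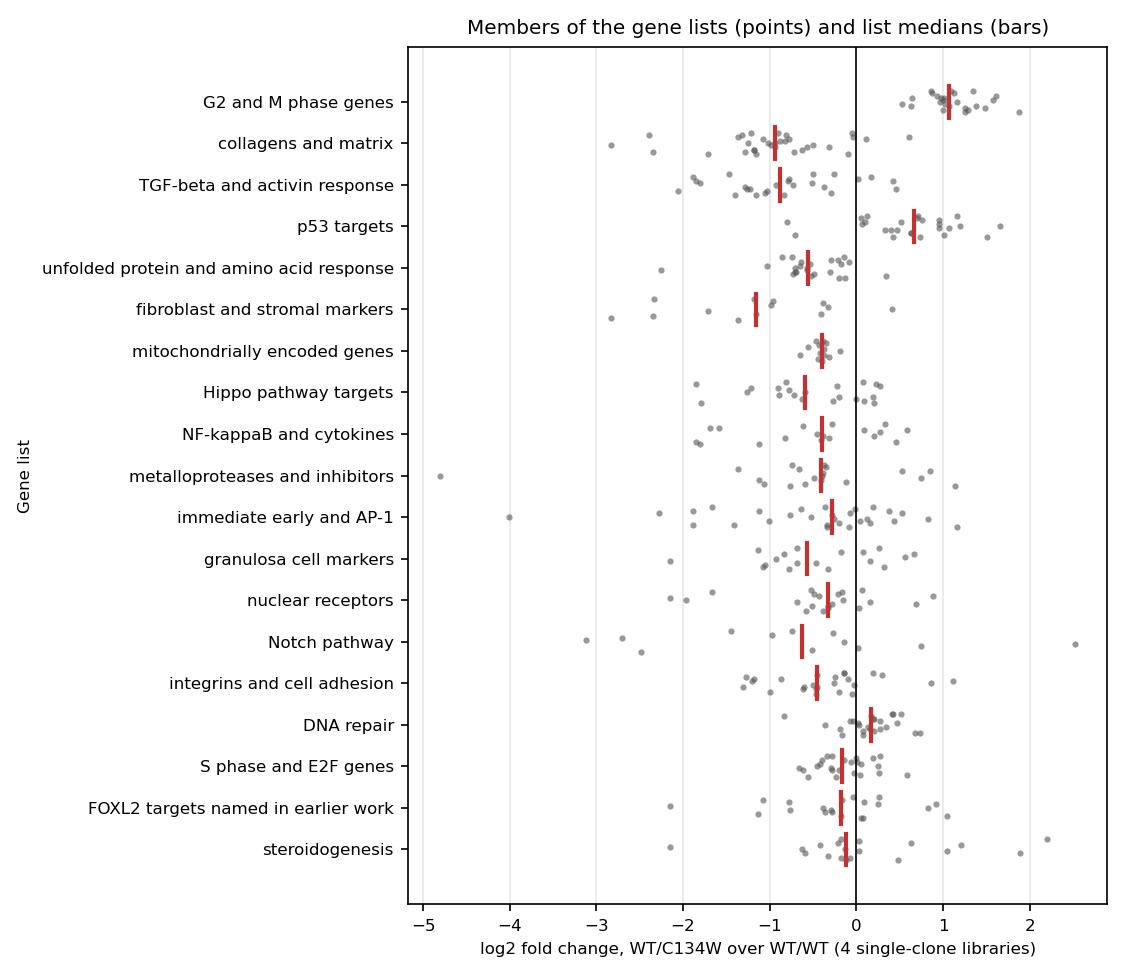
log2 fold change, WT/C134W over WT/WT, of each tested member (points) and the median (red bar) for the 17 gene lists that passed camera with a preset correlation, and for FOXL2 targets and steroidogenesis, which did not. The G2 and M phase members all lie above 0, with a median of 1.07, and the matrix genes have a median of -0.94.

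Of 41 lists tested, 17 passed camera with the preset correlation of 0.01, 3 higher and 14 lower, while 0 passed with an estimated correlation and 0 with fry, which tests whether a list's genes move one way on balance. In fry's mixed test, which asks whether a list's genes change in either direction, 6 lists passed. They were S phase (adjusted p = 0.0318), growth factors and receptors (adjusted p = 0.0318), collagens and matrix (adjusted p = 0.0356), apoptosis regulators (adjusted p = 0.0356), fibroblast and stromal markers (adjusted p = 0.0418) and metalloproteases (adjusted p = 0.0418). Without 44b, 16 lists were called, 6 of them higher, and 12 of the 17 calls remained. With library totals as the only scaling the median of all genes moved to 0.23. The medians of 12 of the called lists then moved by over 1.5 times, to -0.33 for the unfolded protein, -0.17 for the mitochondrial, -0.37 for the Hippo, -0.17 for the NF-kappaB and -0.21 for the metalloprotease list. For the other 7 they were -0.05 for immediate early and AP-1, -0.35 for granulosa cell markers, -0.11 for nuclear receptors, -0.41 for Notch, -0.22 for integrins, 0.39 for DNA repair and 0.05 for S phase. Each of the other 7 calls was lost without 1 of the clones or after a correction for GC content. Granulosa cell markers were lower in 12 of 18 members (median -0.57, adjusted p = 0.0181, adjusted p = 0.51 with an estimated correlation), but the camera call was lost without 44a (adjusted p = 0.101) or without 3.11 (adjusted p = 0.113). Of these markers, IRX3 had 45.3 and 47.7 CPM in the reverted clones and 25.8 and 19.2 CPM in the mutant clones, and it was the 1 member that passed adjusted over the list alone. INHBA, an activin subunit, had 201 and 155 CPM against 66.8 and 120 CPM. Immediate early and AP-1 genes were lower in 20 of 29 (adjusted p = 0.00932, adjusted p = 0.425 with an estimated correlation), 3 of them adjusted over the list alone: SPRY4, EGR1 and JUNB. Integrin and adhesion genes were lower in 21 of 25 (adjusted p = 0.0249, adjusted p = 0.52 with an estimated correlation), a call lost without 4.72 (adjusted p = 0.611) or without 44b (adjusted p = 0.2). ITGAV was lower and NCAM1 higher among them adjusted over the list alone, and these were the 2 that passed. Nuclear receptors (16 of 21 lower, adjusted p = 0.02) lost the call without 4.72 (adjusted p = 0.111) or 44b (adjusted p = 0.0626). Notch pathway genes (9 of 12 lower, adjusted p = 0.0245), with HES1 at -2.71 and HEY1 at 2.53, lost it without 44a (adjusted p = 0.0594) or 44b (adjusted p = 0.2). With an estimated correlation these 2 lists had an adjusted p of 0.425 and an adjusted p of 0.52. DNA repair genes (19 of 25 higher, adjusted p = 0.0262) lost the call without 4.72 (adjusted p = 0.123), 3.11 (adjusted p = 0.136) or 44b (adjusted p = 0.0983). S phase genes (15 of 24 lower, median -0.17, adjusted p = 0.0272) lost it without 44a (adjusted p = 0.549) or 44b (adjusted p = 0.172), and theirs was the median that changed sign with library totals alone. Their adjusted p with an estimated correlation was 0.425 for DNA repair and 0.761 for S phase. In the last 4 of these lists 0 members passed adjusted over the list alone. The difference in mean log2 CPM moved by over 1.5 times without a single clone in 6 of these 7 lists. Without 3.11 it was -0.20 in place of -0.55 for granulosa cell markers, -0.37 in place of -0.56 for immediate early and AP-1 genes and -0.23 in place of -0.38 for nuclear receptors, and the granulosa value was -0.90 without 44b. Without 44a it was -0.51 in place of -0.89 for Notch and -0.07 in place of -0.14 for S phase, which had -0.09 without 44b. For integrins it was -0.17, with -0.48 without 44a and 0.13 without 4.72.

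Fold changes also followed the GC content of the genes. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change with GC content was -0.293. The median log2 fold change ran from 0.18 in the fifth of genes with the lowest GC content to -0.23 in the fifth with the highest. Between clones of one genotype rho was 0.095 (4.72 over 44a) and 0.185 (44b over 3.11). Between single clones of different genotypes it ran from -0.325 (3.11 over 4.72) to -0.107 (44b over 44a), the latter smaller in size than 0.185. For 4.72 and 44b over 44a and 3.11, a split that crosses the genotypes, rho was 0.202. With a loess on GC content removed in each library, 11 of the 17 list calls remained. Those lost were granulosa cell markers, immediate early and AP-1, nuclear receptors, Notch, DNA repair and S phase, with adjusted p of 0.0754, 0.162, 0.362, 0.0871, 0.4 and 0.0652. After a loess of the fold changes on GC content and length, the median of the granulosa markers was -0.54, from -0.57, with a bootstrap interval over members of -0.84 to 0.08. The medians of the other 5 were -0.11 from -0.28, -0.13 from -0.33, -0.38 from -0.62, 0.09 from 0.17 and -0.09 from -0.17, in the order given. The 10 lists described first, from G2 and M phase to mitochondrially encoded genes, were among those that remained, with the Hippo median at -0.35 from -0.59 after that loess. Interferon response genes, not called before (adjusted p = 0.0956), were called as higher in the mutant clones after the correction in each library (adjusted p = 0.0297). Both values are camera's with the preset correlation. With an estimated correlation, computed without the GC correction only, camera's adjusted p for this list was 0.761. After the correction in each library edgeR called 0 of 16395 genes, with 1025 at an unadjusted p under 0.05.

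The lists of FOXL2 targets and of steroidogenesis were not called by camera, which looks for a shift one way. Fry's mixed test, open to both directions, did not call them either (adjusted p = 0.925 and 0.554). Of 30 FOXL2 targets named in earlier work, 20 were tested, 8 higher and 12 lower (median -0.17, camera adjusted p = 0.64). Among them were INHBB at -1.14 ± 0.41, FST, which encodes follistatin, at -0.78 ± 0.41 and STAR at 1.04 ± 0.46. Of 28 steroidogenesis genes, 19 were tested, 8 higher and 11 lower (median -0.12, camera adjusted p = 0.642). Their mean, 0.13, had the opposite sign to the median and the test, and their regulator NR5A1 had 43.6 and 50.1 CPM in the reverted clones and 37.2 and 37.5 CPM in the mutant clones. Both medians turned positive, 0.05 and 0.10, with library totals as the only scaling. Adjusted over the list alone, 0 members of either list passed. Sertoli cell and testis-determination markers (adjusted p = 0.997), with NEDD9 at -1.33 and SOX9 at 1.04, and theca and Leydig cell markers (adjusted p = 0.866) gave no call. NEDD9 was the 1 Sertoli list member that passed adjusted over the list alone. Of the markers of other cell types, the fibroblast and stromal list was called, as lower in the mutant clones, and the leukocyte (adjusted p = 0.997), endothelial (adjusted p = 0.995) and epithelial (adjusted p = 0.47) lists, with 6, 5 and 7 tested members, were not. Germ cell and oocyte markers, with 2 members past the filter on low counts, were not tested as a list. Among the other lists without a call, 3 growth factor and receptor genes and 3 neuronal genes passed adjusted over the list alone.

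At least 2-fold differences in normalised level were found for 2989 genes between 44a and 4.72 and for 3213 genes between 3.11 and 44b. Across genotypes the counts were 4058 (44a and 3.11), 2893 (44a and 44b), 3394 (4.72 and 3.11) and 2520 (4.72 and 44b). The top 2 clones of a gene were the 2 of one genotype for 6505 genes, 39.6% of those tested, against 33.3% by chance. They were 44a with 3.11, or the other pair, for 29.8%, and 44a with 44b, or the other pair, for 30.5%. With edgeR, an unadjusted p under 0.05 was found for 1243 genes in the split by genotype, 363 in the split of 44a and 3.11 from the others and 734 in the split of 44a and 44b from the others. Gaps of at least 2-fold parted 44a and 44b from the others in 672 genes and the genotypes in 429. On the first principal component of the single clones (51.9% of variance) 44a lay at -88, 44b at -22.2, 4.72 at 13.9 and 3.11 at 96.3. The genotypes overlapped there and on the second component (26.1%), and parted on the third (22%).

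**Figure D3:**
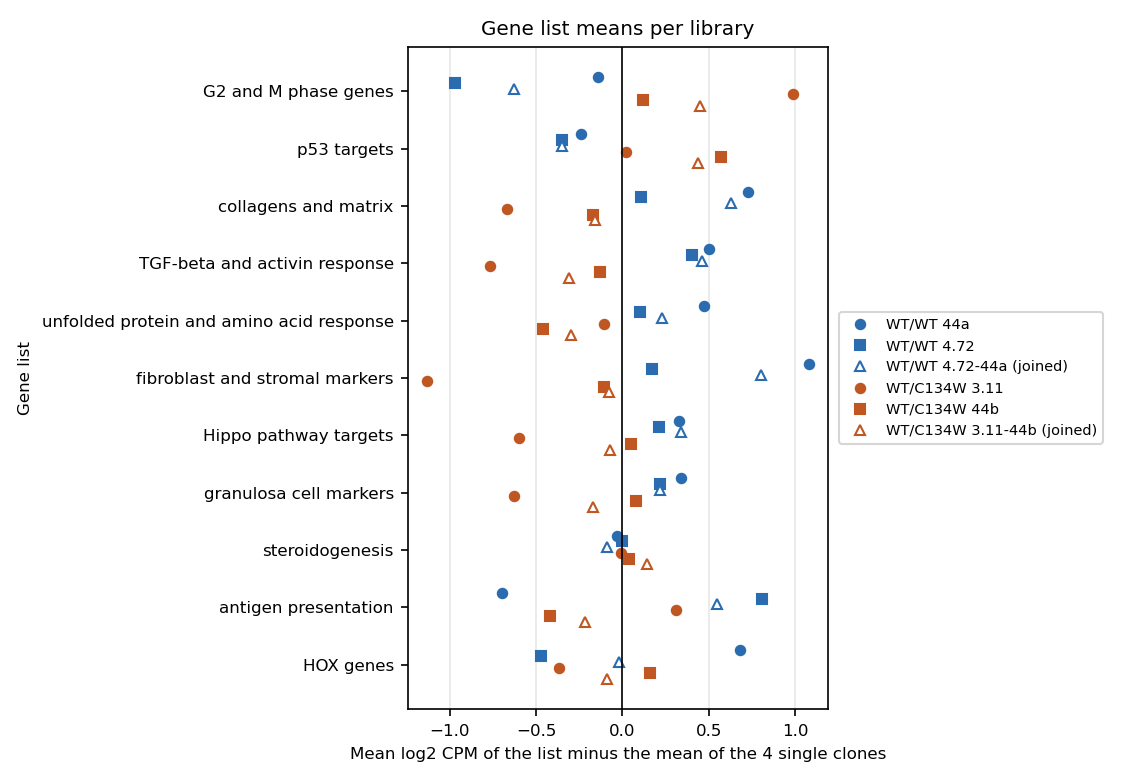
Mean log2 CPM of 11 gene lists in each library, less the mean of the 4 single clones, WT/WT in blue and WT/C134W in orange, with open triangles for the joined libraries. In G2 and M phase genes the reverted clones lie at -0.14 and -0.97 and the mutant clones at 0.99 and 0.12, whereas antigen presentation and HOX genes do not part by genotype.

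For most genes far apart between the clones in their names, the joined libraries took values between those of the clones. This was not so for every gene. FOXL2 had 4.35 CPM in 4.72-44a, below the 4.84 and 7.40 CPM of its clones. In 3.11-44b it had 6.35 CPM, below the 9.30 and 10.1 CPM of its clones. For 205 genes at least 4-fold apart between 44a and 4.72, library 4.72-44a lay between them in 96.1%, at a median of 69.6% of the way from 44a to 4.72. For 181 such genes between 3.11 and 44b, library 3.11-44b lay between them in 91.2%, at a median of 72% of the way to 44b. When the joined library of the other genotype was used in its place, 82.9% and 74% of these genes lay between. The median absolute log2 deviation from a mix at those shares was 0.085 and 0.091, against 0.197 and 0.236 between the single clones. Of genes with an unadjusted p under 0.05 in the 4 single clones, 94.9% had the same sign between the joined libraries, against 68.2% of all tested genes. Neither share is independent evidence if the joined libraries are mixes of the same clones.

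Chromosome medians of the log2 fold change lay within a narrow range. Outside the mitochondrial genome, they ran from -0.11 on chromosome 19 to 0.08 on chromosome 18. Among windows of 10 Mb with at least 10 genes, the furthest from 0 were the one starting at 90 Mb on chromosome 5 (0.31, 23 genes) and the one at 150 Mb on chromosome X (-0.29, 45 genes). In the first of these, 44b lay -0.31 from 3.11, so clones of one genotype differed there by as much. In the second, 4.72 lay 0.033 from 44a and 44b lay 0.197 from 3.11, both smaller in size than the shift between genotypes. Both windows were picked for the size of their shift between genotypes, which was neither tested nor corrected for GC content.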

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

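The GC correction, the tests on all 6 libraries other than edgeR's, the removal of single clones from the 6-library test and from the list means, and the list medians under other scalings were chosen after the data were seen. The count of 0 genes stayed at 0 with limma voom, median-ratio size factors, library totals alone, the filter of 10 CPM, log2(TPM + 1) with or without a TPM filter, the 1.5-fold test, stricter thresholds, the GC correction and each single clone left out (0 to 0 calls, where the lone clone is assumed to vary like the other genotype). It became 511 with all 6 libraries, 283 with DESeq2, of which 245 are among the 511, 664 without a low-count filter, 5 with the block of clone names and 2 with log2(TPM + 0.1), the small RNA genes RNA5S9 and SNORD89, neither of which passed the filter on low counts of the edgeR test. Without the filter the prior degrees of freedom of edgeR went from 3.71 to infinite, and 637 of the 664 genes are among those tested with the filter. Stricter thresholds could only leave the count at 0, and the 1.5-fold test asks for more than the main test. The 5 blocked calls, all lower in WT/C134W, were C1orf198, FBXO32, CRIP2, TIMP3 and ATP10A. With single clones left out, the log2 fold change ran from -15.432 to 10.638 for TIMP3 expression and from -14.1 to 7.341 for ATP10A expression, both positive without WT/WT replicate 1, the clone that holds most of their counts. Where the clone left alone in a genotype had 0 counts, as for the ends of both these ranges, -13.536 for DSG2 and 12.404 for PCDH7, the fitted value depends on the prior count and measures no fold change. The 6 other genes chosen after their values were seen, which part the clones across the genotypes, also changed sign. With single clones left out the range was -4.474 to 5.6 for KRT14 expression, -13.536 to 2.115 for DSG2 expression, -2.74 to 3.145 for CD74 expression, -5.454 to 2.131 for CHRDL1 expression, -1.886 to 12.404 for PCDH7 expression and -6.666 to 7.151 for IGF2BP1 expression. From a negative value, KRT14 turned to 0.473 with limma voom, 0.185 with the block and 0.115 on the log2(TPM + 1) scale. DSG2 turned to 0.373 with all 6 libraries, 0.086 with library totals alone and 0.209 and 0.063 without the joined WT/WT or WT/C134W library. CD74 turned to 0.138 with limma voom and 0.004 with the block, PCDH7 to 4.508, 1.649 and 0.685 with limma voom, the block and log2(TPM + 1), and IGF2BP1 to 0.193 with limma voom. For the other alternatives the cause was not tested. The 511 calls became 1487 with DESeq2 and 551 with limma voom on 6 libraries, and 6 to 590 with single libraries left out: 29 and 6 without the joined WT/WT or WT/C134W library, 88 without 4.72 and 286 without 44b. The fold change of FOXL2 kept its sign in the alternatives run for it (0.39 to 0.99 with single clones left out) and did not pass the threshold in them, with adjusted p from 0.286 to 1. It was not computed with the GC correction, log2(TPM + 0.1), no TPM filter, the 1.5-fold test, or DESeq2 and limma voom on 6 libraries. The rule for the 24 named genes required no overlap between the genotypes and the same sign in the joined libraries, so their sign under the alternatives says nothing about stability. Of the 17 list calls 0 held with an estimated correlation and 0 with fry, and 17 held with all 6 libraries. If the joined libraries are mixes, that fit counts the same clones again, so the 17 are not independent evidence. With the GC correction 11 held and 12 were called, interferon response being the one gained. With single clones left out 16 to 18 lists were called, and 14, 14, 15 and 12 of the 17 calls remained without 44a, 4.72, 3.11 and 44b. Without 44b 6 lists were higher, against 3. With library totals alone the median of all genes moved to 0.23, and the S phase median turned to 0.054. The difference in list means of the integrins ran from -0.48 to 0.13 with single clones left out, positive without 4.72. The agreement in sign of the joined libraries was 91.2% on the log2(TPM + 1) scale against 94.9%, and the mixture shares with an 8-fold minimum were 69.6% and 70.2%. The simulations put the limit of depth and clone number at 10.3% recovery of 2-fold changes.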

Other observations

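The simulation with recounted clones and the count of lists under other pairings of the clones were chosen after the results were seen, and the GC tests were chosen after the trend across all genes was seen but before any list was corrected. The 4 clones also parted along a line that crosses the genotypes, 44a and 44b, which share a stem in their names, on one side and 4.72 and 3.11 on the other. The single genes of this paragraph and the next were chosen after their values were seen, and none of them has a fold change between genotypes that keeps its sign in every alternative run. KRT14, a basal keratin, had 100.2 CPM in 44a and 48.6 CPM in 44b, against 0.518 in 4.72 and 2.27 in 3.11. DSG2, a desmosomal cadherin, had 63.1 and 65.7 CPM in 44a and 44b, against 7.53 and 0 CPM. CD74, the invariant chain of class II antigen presentation, had 2.67 and 8.18 CPM in 44a and 44b but 107 and 39.3 CPM in 4.72 and 3.11, and CHRDL1, a BMP antagonist, had 10.3 and 2.10 CPM against 173 and 88.8 CPM. A gap of at least 2-fold between the 2 pairs was found for 672 genes in this split, 429 in the genotype split and 377 in the third. In edgeR's test 1 gene was called in this split, IGF2BP1, an RNA-binding protein of fetal tissues, with 39.6 and 28.9 CPM against 0.1 and 0.19 CPM (adjusted p = 0.0481).

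Camera called 8 gene lists in this split, 5 of which did not overlap between the pairs in their means. Of those 5, glycolysis and hypoxia (camera adjusted p = 2.33e-11), antigen presentation (0.000637) and lipid synthesis (0.0119) were lower in 44a and 44b, and HOX genes (0.0253) and epithelial markers (0.0444) were higher, all with the preset correlation. The other 3, p53 targets (0.0253), mitochondrially encoded genes (0.0444) and cholesterol synthesis (0.0444), overlapped between these pairs, and the first 2 did not overlap between the genotypes. Clone 44a stood apart in single genes. TIMP3, an inhibitor of metalloproteases, had 263 CPM in 44a, 9.37 in 44b and 0 in 4.72 and 3.11, where 3 counts would be 0.0666 and 0.0784 CPM, and PCDH7, a protocadherin, had 0 CPM in 44a against 56.8, 20.4 and 10.7 CPM in 4.72, 3.11 and 44b.

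The 511 genes called with all 6 libraries against 0 with the 4 single clones may come from counting clones again. Simulated data with no genotype effect, 4 clones and 2 mixes of them gave 521.2 calls on average, against 1 call with 6 independent clones. The simulated mixes held counting noise alone, so the nearness of 521.2 to 511 does not measure how many calls come from recounting. A simulation does not show that the 511 genes hold no effect of genotype, and DESeq2 on the 4 clones called 283 genes against 51.8 in simulations without effect. In those simulations each gene varied on its own between clones, and DESeq2 was not run on the other pairings of the clones. The excess over 51.8 therefore cannot tell genotype from clone differences. Of the 10 splits of the 6 libraries 1, the real one, gave as many calls (511, the highest other 0), and 10 splits are too few for a share under 0.05. Every other split also sets a joined library against a clone in its own name. If the joined libraries are mixes, few calls there follow from the design, so the 0 does not argue for a genotype effect.

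The number of gene lists called between genotypes, 17, could come from clones that differ in these lists whatever their genotype. The other 2 ways to pair the clones called 4 and 8 lists, and both lie under the bound of 8.5, 0.5 times the 17, that had been written down as arguing against this explanation after the list means of each library had been seen. Leaving out single clones gives 16 to 18 lists and so a bound of 8 to 9, which the 8 does not clear, but this allowance for spread was itself adopted after the 8 was seen. With 3 ways to pair 4 clones the genotype comes first by chance in 33.3%, so genotype and clone cannot be told apart for the lists as a whole. The editing procedure, named in the labels of the WT/WT samples alone, stays open too, untested.

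The higher G2 and M phase genes and the lower matrix and TGF-beta genes in WT/C134W were set against the GC trend of the fold changes. After a loess on GC content and gene length, the median log2 fold change of the G2 and M phase genes was 1.05, from 1.07. It was -0.77 for collagens and matrix, from -0.94, and -0.81 for the TGF-beta and activin response, from -0.88. The bootstrap intervals over members, 0.84 to 1.20, -0.999 to -0.645 and -1.12 to -0.45, leave out a halving, the last by a small margin. They measure the spread over members, which are not independent replicates, and not the spread between clones. For the members in these clones, the values argue against GC content and length as the whole cause. A genotype effect stays a hypothesis, since clone differences remain open and camera also called the G2 and M phase list between 44a with 3.11 and 4.72 with 44b (adjusted p = 1.7e-11).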
